A study of Mus musculus with 41 samples.

How the data were processed

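Cells were sorted by flow cytometry, RNA was isolated with the AllPrep Micro kit, and libraries were made with the SMARTer Stranded Total RNA-Seq kit, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.17.1.14 and aligned with TopHat2 2.1.0 to mm10 (GRCm38), per the submitters' processing notes. The authors deposited 1 table of raw counts per gene, whole numbers without normalization, for 41 libraries and 19434 genes. The annotation, the strand setting and the counting settings were not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

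Genes were taken by the symbol in the table, because 3411 of its identifiers carry another symbol in the GENCODE reference. The 13 mitochondrial genes hold 0 counts in every library, and Xist, Malat1 and Rn45s are absent from the table, so these signs of RNA quality could not be read. Total counts ran from 781437 to 5709702 per library. No pair of libraries of a group agreed within sampling noise (smallest chi-square per degree of freedom 2.60).

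Libraries were grouped by genotype and sorted population from the labels, which call them biological replicates. Tests used edgeR 4.0.16 in R 4.3.3: TMM factors, the default expression filter by group, robust quasi-likelihood fits and 2-sided F-tests, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The chimera fit held 8 libraries and 9569 genes, and the pulse-chase fit held 33 libraries in 6 groups and 9921 genes. Common biological coefficients of variation were 0.134 and 0.215. Log2 fold changes are given ± SE, and levels as mean CPM of the TMM-scaled library ± SD. Marker sums are CPM of the total count.

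Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. They cover Treg core, effector Treg, naive and central T cell, helper cell (Th1 and cytotoxic, Th2, Th17, follicular helper), inhibitory receptor, chemokine receptor, S phase, G2/M, p53, DNA methylation, germline, imprinted, interferon, NF-kB, immediate early, glycolysis and oxidative phosphorylation genes. Others hold markers of B, myeloid, NK, CD8, thymocyte, erythroid and stromal cells.

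The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule takes Uhrf1 and Foxp3 everywhere, the 8 (leading comparisons) or 4 (others) largest called changes in each direction among genes with a mean log2 CPM of at least 4, leaving out predicted, pseudo-, receptor segment, mitochondrial and ribosomal genes, and from lists that passed or held 3 called members the 4 called members with the smallest p and the 2 most abundant members not called. It gives 479 pairs of a gene and a comparison. The text names 155 pairs, a part chosen with the results in view, so the named genes are examples and not a random sample of the calls. Some genes are not reported here. Nnt, Ifngr2, Sesn1 and Pydc3 outside their leading comparisons, Gbp1, and Igj between genotypes, lie outside the rule and were chosen after their values were seen.

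The pipeline was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 85 and 95 in the chimera (9465 genes) and 75 and 87 in labeled genotype (9789 genes). Replicate numbers recur across groups, and the labels do not say that a number marks a mouse. Same-numbered libraries deviated together (every correlation above 0.1) in the labeled genotype comparison (0.105 to 0.351), in ex-Foxp3 against labeled cells of controls (0.209 to 0.340) and fl/fl mice (0.201 to 0.404), and in labeled against post-tamoxifen fl/fl cells (0.254 to 0.469). There a fit blocked by number stands beside results it changes, though labeled genotype pairs no mice.

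Alternatives fixed beforehand were other scaling factors, other count filters, DESeq2 1.42.0, the replicate block, fits of the compared groups alone and leaving out each library. Chosen after seeing the data were the split of pulse-chase numbers into 1 to 3 and 4 and above, fits without doubted libraries, and a myeloid marker term. Pulse-chase controls 2 and 3 held Y-linked reads in all 3 populations (328 to 456 CPM, others at most 2.31), which ties number to mouse. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.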

Results

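RNA was sequenced from 41 libraries of sorted mouse CD4 T cells, from a pair of experiments on Uhrf1, whose product guides the copying of DNA methylation after replication. In the chimera experiment, CD25-high Treg cells with a Foxp3-YFP reporter came from females. Chimeric knockouts carried 2 floxed Uhrf1 alleles and Foxp3-Cre on 1 X chromosome (n = 4), and controls had intact Uhrf1 and Cre (n = 4). In the pulse-chase experiment, Cre under Foxp3 was active only with tamoxifen, and a tdTomato reporter marked cells in which it had acted. Mice ate tamoxifen chow for 2 weeks and standard chow for 4 weeks, and the labels give an age of 8 weeks for all. Labeled Treg cells (Foxp3-GFP and tdTomato positive), ex-Foxp3 cells (tdTomato positive only) and post-tamoxifen Treg cells (GFP positive only) were sorted from Uhrf1 fl/fl mice (n = 6 libraries of each) and controls (n = 5 of each).

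Total counts per chimera library were 3141687 to 5709702 in controls and 2403189 to 4594977 in chimeric knockouts. Pulse-chase controls held 1153730 to 2609699 counts in labeled, 1589473 to 3435802 in ex-Foxp3 and 781437 to 3153563 in post-tamoxifen cells. For fl/fl mice the ranges were 1052731 to 2553989, 2095699 to 2665449 and 1172214 to 2600299.

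Uhrf1 (mm10, chromosome 17, 56303321 to 56323486, plus strand) was the targeted gene. Its level was 13.1 ± 6.35 against 25.2 ± 4.92 CPM (SD, n = 4 each) in chimeric knockouts against controls (log2 fold change -0.95 ± 0.25 (SE), adjusted p = 0.0378). Knockout libraries 1 to 3 held 12.0, 8.66 and 9.27 CPM, and controls 1 to 4 held 32.5, 22.4, 23.4 and 22.3 CPM. The library labelled chimeric knockout 4 held 22.3 CPM, at the level of the controls. The call was lost without any 1 library except the library labelled chimeric knockout 4 (adjusted p up to 0.162), with DESeq2 (adjusted p = 0.0733) and without controls 3 and 4 (adjusted p = 0.127). In labeled cells it was 46.2 ± 34.3 against 50.6 ± 38.2 CPM (SD, n = 6 and n = 5) in fl/fl against control mice, a difference not detectable at this spread (log2 fold change -0.15 ± 0.60, adjusted p = 0.961). Ex-Foxp3 cells held 16.7 ± 7.74 against 19.4 ± 10.2 CPM (SD, n = 6 and n = 5, log2 fold change -0.20 ± 0.68, adjusted p = 0.976). Post-tamoxifen cells, without the recombination label, held 84.9 ± 65.1 against 29.9 ± 18.7 CPM (SD, n = 6 and n = 5, log2 fold change 1.62 ± 0.64, adjusted p = 0.113). The floxed exons were not given in the sources used here, and counts over a whole gene do not show which exons the reads came from.

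Foxp3 (mm10, chromosome X, 7579676 to 7595243, plus strand) encodes the transcription factor that defines Treg cells. In fl/fl mice it was at 61.1 ± 38.2 against 380.1 ± 65.8 CPM (SD, n = 6 each) in ex-Foxp3 against labeled cells (log2 fold change -2.63 ± 0.37, adjusted p = 5.33e-05). In controls it was at 109 ± 29.3 against 406 ± 16.5 CPM (SD, n = 5 each, log2 fold change -1.90 ± 0.39, adjusted p = 0.0235), a call lost without ex-Foxp3 library 1, 4 or 5 or labeled library 2 or 3 (adjusted p up to 0.0998). Between genotypes it did not pass in the chimera (0.38 ± 0.13, adjusted p = 0.176), in labeled (-0.094 ± 0.35, adjusted p = 0.96), in ex-Foxp3 (-0.82 ± 0.38, adjusted p = 0.521) or in post-tamoxifen cells (-0.14 ± 0.35, adjusted p = 0.856). Control post-tamoxifen library 2 held Foxp3 at 123 CPM, and the other libraries of that group at 365 to 537 CPM. Post-tamoxifen fl/fl library 3 held 128 CPM, and the others of its group up to 458 CPM.

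**Figure D1:**
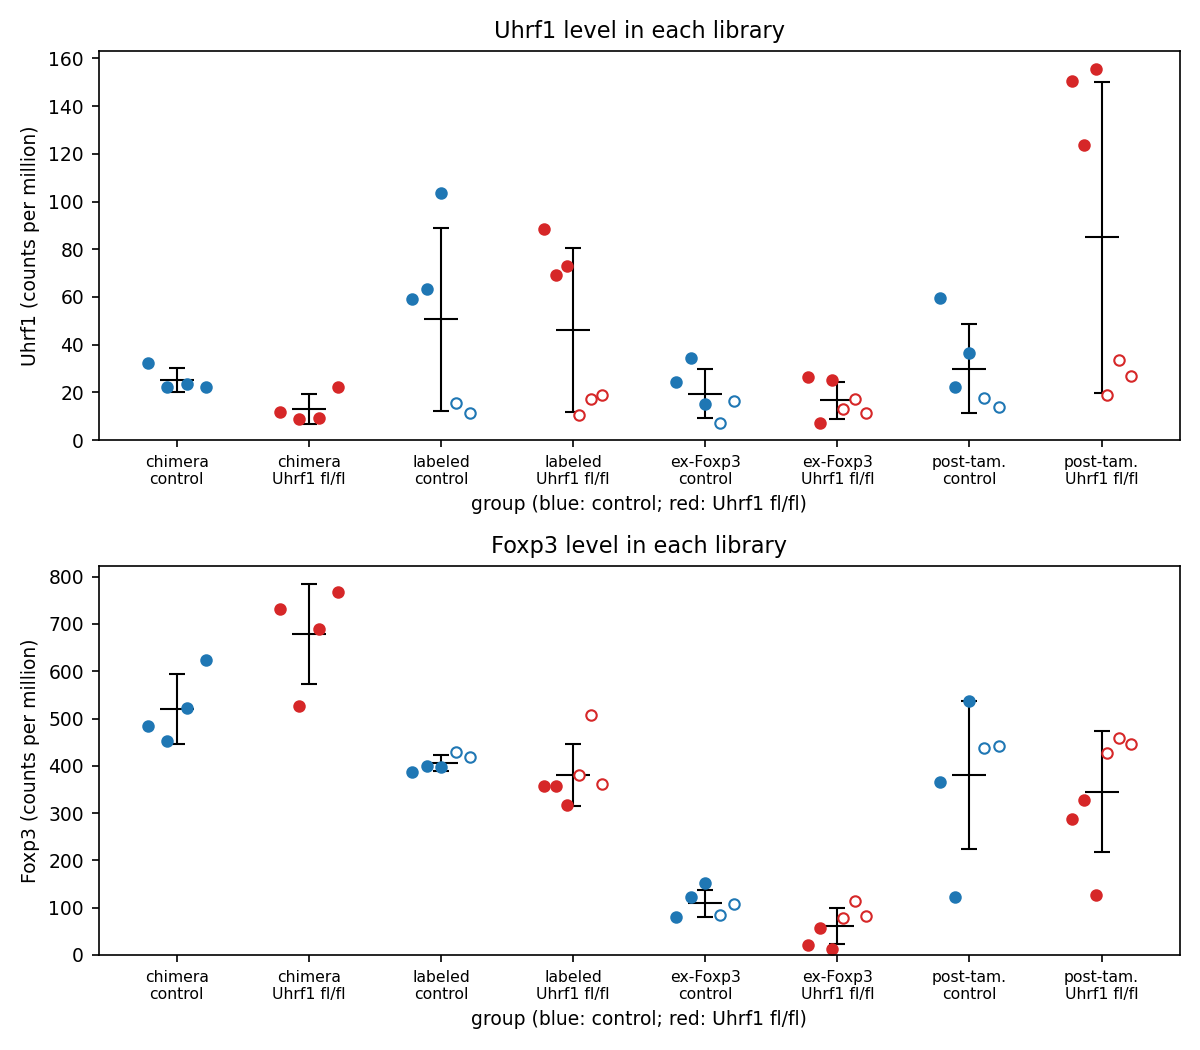
Levels in CPM of Uhrf1 and Foxp3 in each library of the 8 groups, with the mean and SD as bars and open circles for pulse-chase numbers 4 and above. Foxp3 lies lowest in the ex-Foxp3 groups, and Uhrf1 spreads widely within labeled and post-tamoxifen groups.

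The chimera comparison asks which transcripts differ in Treg cells of chimeric mice whose Cre-bearing cells carry floxed Uhrf1. Genes of the naive and central T cell list were among those that rose. S1pr1, a receptor for exit from lymphoid tissue, was at 613 ± 97.1 against 436 ± 27.1 CPM (SD, n = 4 each, log2 fold change 0.49 ± 0.089, adjusted p = 0.00297). Bach2, a repressor of effector differentiation, rose with it (0.39 ± 0.079, adjusted p = 0.00483). Genes of the follicular helper list were among those that fell. Pdcd1, which encodes PD-1, was at 31.8 ± 10.5 against 79.0 ± 14.9 CPM (SD, n = 4 each, log2 fold change -1.34 ± 0.20, adjusted p = 0.00142). The regulator Tox2 (-1.97 ± 0.28) and the follicle homing receptor Cxcr5 (-0.62 ± 0.14) also fell (adjusted p of at most 0.0152). edgeR called 231 of 9569 genes tested, 82 higher and 149 lower in chimeric knockouts.

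Abundant genes that rose included Ccrn4l (1.51 ± 0.23), a circadian deadenylase, Pde3b (1.05 ± 0.26), a phosphodiesterase, Ly6c1 (0.93 ± 0.20), Gpr83 (0.80 ± 0.095) and Itm2a (0.78 ± 0.15), with adjusted p of at most 0.0444. The chemokine receptor gene Ccr2 rose from a low level, 14.8 ± 7.71 against 2.49 ± 0.281 CPM (SD, n = 4 each, log2 fold change 2.52 ± 0.41, adjusted p = 0.00034). Naip5 (-2.59 ± 0.30), Naip6 (-2.02 ± 0.19), Naip2 (-1.48 ± 0.22) and Nlrp1b (-1.60 ± 0.25), which encode inflammasome sensors, fell (adjusted p of at most 0.00139). The Naip genes and Ly6c1 have close paralogs, so their separate values are uncertain. The calcium channel gene Ryr2 (-2.22 ± 0.26) and Nav2 (-2.14 ± 0.27) fell as well (adjusted p of at most 0.00941).

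Of 20 naive and central T cell genes tested, 5 rose (10 rose and 1 fell adjusted over the list), median 0.26 (adjusted p = 5.34e-08, or 0.136 with estimated correlation). Of 12 follicular helper genes tested, 3 fell (6 fell adjusted over the list), median -0.48 (adjusted p = 1.76e-12, or 0.103 with estimated correlation). Of 9 inhibitory receptor genes tested, 2 fell (3 fell adjusted over the list), median -0.45 (adjusted p = 1.58e-06, or 0.113 with estimated correlation). Of 29 Treg core genes tested, 2 rose and 4 fell (3 rose and 9 fell adjusted over the list), median -0.26 (adjusted p = 1.23e-06, or 0.475 with estimated correlation). In the last list Gpr83 and Ecm1 (0.64 ± 0.10) rose, and Nrp1 (-0.75 ± 0.093), a semaphorin receptor, and Ebi3 (-2.20 ± 0.31), a cytokine subunit, fell (adjusted p of at most 0.0002). Of 24 effector Treg genes tested, 1 rose and 4 fell (1 rose and 7 fell adjusted over the list), median -0.29 (adjusted p = 5.2e-06, or 0.52 with estimated correlation). Gata3 (-0.46 ± 0.10) and Id2 (-1.09 ± 0.24), transcriptional regulators, were among those that fell (adjusted p of at most 0.0165).

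Of 6 Th17 genes tested, 2 fell (3 fell adjusted over the list), median -0.65 (adjusted p = 3.93e-05, or 0.113 with estimated correlation). Ccr6 (-0.74 ± 0.20), a chemokine receptor, and Ahr (-0.66 ± 0.17), a ligand-activated transcription factor, fell (adjusted p of at most 0.0387). Of 17 Th1 and cytotoxic genes tested, 1 rose and 1 fell (1 rose and 3 fell adjusted over the list), median -0.36 (adjusted p = 0.00907, or 0.382 with estimated correlation). Eomes, a transcription factor of cytotoxic cells, rose against that shift (1.46 ± 0.35, adjusted p = 0.0304). Of 7 Th2 genes tested, 1 fell (3 fell adjusted over the list), median -0.46 (adjusted p = 0.003, or 0.185 with estimated correlation). Of 21 NF-kB targets tested, none passed (9 fell adjusted over the list), median -0.23 (adjusted p = 2.25e-05, or 0.136 with estimated correlation). Of 20 chemokine receptor and homing genes tested, 3 rose and 4 fell (5 rose and 5 fell adjusted over the list), median -0.052 (adjusted p = 0.594, or 0.711 with estimated correlation). The integrin Itgb1 (-0.74 ± 0.11) fell (adjusted p = 0.00159). Of 37 interferon-stimulated genes tested, 1 rose (1 rose adjusted over the list), median 0.090 (adjusted p = 0.0126, or 0.711 with estimated correlation). Its member Ly6a rose (0.77 ± 0.19, adjusted p = 0.0223).

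Chimera controls 3 and 4 held summed B cell and plasma cell markers at 349 and 388 CPM, and the other 6 libraries at 35.2 to 65.3 CPM. The B cell list lay lower in chimeric knockouts (0 of 4 called or 0 adjusted over the list, median -1.97, adjusted p = 0.00217, or 0.388 with estimated correlation). Summed G2/M transcripts were at 724 and 639 CPM in these controls and 197 to 363 CPM in the others. G2/M genes lay lower in chimeric knockouts (0 of 21 called or 0 adjusted over the list, median -0.68, adjusted p = 0.000897, or 0.695 with estimated correlation), and the S phase list gave adjusted p = 0.0896. Without controls 3 and 4, 95 genes were called, losing Ly6c1, Itm2a, S1pr1, Bach2, Nav2, Cxcr5, Pde3b, Ahr, Ccr6, Id2 and Eomes (adjusted p up to 0.401). DESeq2 did not call Ccr6 (adjusted p = 0.067). Control 1 held Y-linked transcripts at 423 CPM. Leaving out 1 library changed the count to 118, 150, 115 and 121 without control library 1, 2, 3 or 4 and 150 and 100 without chimeric knockout library 1 or 2, and 352 without the library labelled chimeric knockout 4, whose Uhrf1 lay at the level of the controls. Calls were lost for Gata3 without control library 1 or chimeric knockout library 1 or 2 (adjusted p up to 0.0751), Cxcr5 without control library 3 or 4 or chimeric knockout library 2 (adjusted p up to 0.101), Ly6c1 without chimeric knockout library 2 (adjusted p = 0.125), and without any 1 library except those in parentheses, Ccrn4l (control 3 and chimeric knockout 1, adjusted p up to 0.0996), Pde3b (that labelled chimeric knockout 4, adjusted p up to 0.133), Ly6a (control 3 and 4 and chimeric knockout 3, adjusted p up to 0.0928), Ahr (control 2 and chimeric knockout 3 and that labelled chimeric knockout 4, adjusted p up to 0.133), Ccr6 (control 2 and that labelled chimeric knockout 4, adjusted p up to 0.17), Eomes (control 2 and chimeric knockout 2 and that labelled chimeric knockout 4, adjusted p up to 0.124) and Id2 (control 1 and that labelled chimeric knockout 4, adjusted p up to 0.0797).

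In labeled Treg cells, which had Foxp3 at tamoxifen and 4 weeks later, 1 gene was called between genotypes. Pydc3, an interferon-inducible gene, was lower in fl/fl mice, at 59.2 ± 11.4 against 113 ± 13.5 CPM (SD, n = 6 and n = 5, log2 fold change -0.95 ± 0.15, adjusted p = 0.00207). Gene lists passed with the preset correlation, although none of their members passed alone. Of 20 naive and central T cell genes tested, none passed (7 fell adjusted over the list), median -0.45 (adjusted p = 5.08e-10, or 0.029 with estimated correlation). Of 10 inhibitory receptor genes tested, none passed (3 rose adjusted over the list), median 0.29 (adjusted p = 0.000527, or 0.029 with estimated correlation). Of 16 p53 targets tested, none passed (1 rose adjusted over the list), median 0.15 (adjusted p = 0.0068, or 0.029 with estimated correlation). These 3 lists passed with both correlations. Of 28 effector Treg genes tested, none passed (5 rose adjusted over the list), median 0.58 (adjusted p = 5.08e-10, or 0.25 with estimated correlation). Of 22 Th1 and cytotoxic genes tested, none passed (3 rose adjusted over the list), median 0.65 (adjusted p = 4.16e-07, or 0.25 with estimated correlation).

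Cell division lists lay higher in fl/fl labeled cells without a called member, S phase (0 of 30 called or 0 adjusted over the list, median 0.40, adjusted p = 0.00147, or 0.705 with estimated correlation) and G2/M (0 of 29 called or 0 adjusted over the list, median 0.78, adjusted p = 0.00795, or 0.705 with estimated correlation). The Treg core (0 of 29 called or 0 adjusted over the list, median 0.15, adjusted p = 0.008, or 0.572 with estimated correlation) and glycolysis lists (0 of 17 called or 0 adjusted over the list, median 0.19, adjusted p = 0.0434, or 0.572 with estimated correlation) shifted as well. Follicular helper genes lay higher (0 of 15 called or 2 adjusted over the list, median 0.25, adjusted p = 0.00872, or 0.572 with estimated correlation), and gave adjusted p = 0.0548, or 0.476 with estimated correlation, with the replicate number as a block. Interferon-stimulated genes gave adjusted p = 0.0656, and with the block adjusted p = 0.00635, or 0.476 with estimated correlation. The naive list median was -0.53 in numbers 1 to 3 and -0.31 in 4 and above (adjusted p = 4.32e-10 and 7.39e-10, or 0.0807 and 0.137 with estimated correlation). For effector Treg genes it was 0.70 in numbers 1 to 3 and 0.46 in 4 and above (adjusted p = 6.42e-15 and 4.64e-11, or 0.106 and 0.202 with estimated correlation). Leaving out 1 library changed the count of called genes to 3 without control library 5 and 2, 9 and 9 without fl/fl library 3, 4 or 6. The block gave 149 genes, a fit of the labeled groups alone 41, numbers 1 to 3 alone 71, and numbers 4 and above 7. Without control numbers 2 and 3, which held Y-linked reads, Pydc3 missed the threshold (adjusted p = 0.0809).

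Ex-Foxp3 cells, which had lost Foxp3 after tamoxifen, differed by genotype in 18 genes, 2 higher and 16 lower in fl/fl mice. Nnt, a mitochondrial transhydrogenase gene, was at 24.0 ± 3.55 against 57.2 ± 7.24 CPM (SD, n = 6 and n = 5, log2 fold change -1.26 ± 0.15, adjusted p = 2.82e-06). Ifngr2 (-1.35 ± 0.24), an interferon gamma receptor subunit, Sesn1 (-1.22 ± 0.19), a stress-response gene, and Acvr1b (-1.05 ± 0.20), an activin receptor, fell (adjusted p of at most 0.00759). Bach2 (-1.09 ± 0.24) and Actn1 (-0.96 ± 0.21), of the naive list, fell too (adjusted p of at most 0.0449). Pogk (1.20 ± 0.26) and Hip1r (0.51 ± 0.11), an endocytic adaptor, rose (adjusted p of at most 0.0415).

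Of 20 naive and central T cell genes tested, 2 fell (1 rose and 11 fell adjusted over the list), median -0.53 (adjusted p = 2.33e-11, or 0.0408 with estimated correlation). Of 22 Th1 and cytotoxic genes tested, none passed (12 rose adjusted over the list), median 0.99 (adjusted p = 1.15e-12, or 0.0551 with estimated correlation). Of 28 effector Treg genes tested, none passed (11 rose adjusted over the list), median 0.62 (adjusted p = 1.08e-11, or 0.211 with estimated correlation). The p53 target (0 of 16 called or 1 adjusted over the list, median 0.14, adjusted p = 0.0091, or 0.0408 with estimated correlation), Th17 (0 of 8 called or 1 adjusted over the list, median 0.58, adjusted p = 0.00971, or 0.445 with estimated correlation) and interferon-stimulated lists (0 of 37 called or 1 adjusted over the list, median 0.22, adjusted p = 6.56e-05, or 0.445 with estimated correlation) lay higher. The Th1 and cytotoxic median was 1.25 in numbers 1 to 3 and 0.54 in 4 and above (adjusted p = 1.08e-19 and 5.45e-07, or 0.0168 and 0.0689 with estimated correlation). For the naive list it was -0.67 in numbers 1 to 3 and -0.37 in 4 and above (adjusted p = 2.77e-10 and 4.56e-13, or 0.0451 and 0.0618 with estimated correlation). Summed NK markers were at 31.4 and 14.8 CPM in fl/fl libraries 1 and 3, 1.11 to 4.28 in the other fl/fl and 0 to 6.40 in control libraries. CD8 markers were at 61.0 and 41.9, 17.1 to 25.3 and 24.1 to 32.9 CPM in the same order. Leaving out 1 library changed the count to 6, 6 and 9 without control library 1, 2 or 3 and 6, 8, 5 and 56 without fl/fl library 1, 2, 3 or 6, and calls were lost for Hip1r without control library 1, 2 or 3 or fl/fl library 1, 2 or 3 (adjusted p up to 0.165), and without any 1 library except those in parentheses, Bach2 (control 4 and 5 and fl/fl 6, adjusted p up to 0.173), Actn1 (control 4 and fl/fl 6, adjusted p up to 0.173) and Pogk (fl/fl 4, 5 and 6, adjusted p up to 0.127). A fit of the ex-Foxp3 groups alone called 137 genes. Numbers 1 to 3 alone gave 143, losing Ifngr2 and Pogk (adjusted p up to 0.0887), and numbers 4 and above 5, losing every gene named except Nnt (adjusted p up to 0.847). A fit without control numbers 2 and 3 gave 5, losing Bach2, Actn1, Acvr1b, Pogk and Hip1r (adjusted p up to 0.2). With no filter on low counts Bach2, Actn1 and Pogk (adjusted p up to 0.0741) were not called.

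The post-tamoxifen genotype comparison concerns cells without tdTomato, the recombination label. It called 717 genes, 387 higher and 330 lower in fl/fl mice. The costimulatory receptor gene Icos rose, at 242 ± 103 against 91.4 ± 36.5 CPM (SD, n = 6 and n = 5, log2 fold change 1.37 ± 0.24, adjusted p = 0.00104). Itgae (2.46 ± 0.50), an integrin, Gzmb (4.00 ± 1.005), granzyme B, Il1rl1 (1.86 ± 0.49), an alarmin receptor, and Il10 (3.43 ± 0.72), a suppressive cytokine, rose as well (adjusted p of at most 0.0202). Inhibitory receptor genes that rose included Havcr2 (4.14 ± 0.90), Tigit (1.83 ± 0.38), Ctla4 (0.84 ± 0.18) and Entpd1 (1.02 ± 0.19), with adjusted p of at most 0.00503. Naive T cell regulators Lef1 (-0.88 ± 0.17), Bach2 (-1.02 ± 0.23) and Foxp1 (-0.59 ± 0.14) and the actin crosslinker Actn1 (-0.77 ± 0.20) fell (adjusted p of at most 0.02).

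Of 28 effector Treg genes tested, 15 rose (22 rose adjusted over the list), median 1.29 (adjusted p = 1.87e-17, or 0.0643 with estimated correlation). Maf (1.25 ± 0.24), Batf (0.75 ± 0.17) and S100a6 (1.99 ± 0.53) were among them (adjusted p of at most 0.0209). Of 10 inhibitory receptor genes tested, 5 rose (7 rose adjusted over the list), median 0.87 (adjusted p = 4.12e-06, or 0.0116 with estimated correlation). Of 29 Treg core genes tested, 9 rose (12 rose adjusted over the list), median 0.47 (adjusted p = 1.43e-08, or 0.0802 with estimated correlation). Of 20 naive and central T cell genes tested, 5 fell (12 fell adjusted over the list), median -0.52 (adjusted p = 1.43e-08, or 0.0551 with estimated correlation). Of 22 Th1 and cytotoxic genes tested, 5 rose (13 rose adjusted over the list), median 0.86 (adjusted p = 1.85e-06, or 0.17 with estimated correlation). Nkg7, of cytotoxic granules, rose (1.96 ± 0.52, adjusted p = 0.0203). The Th2 (2 of 8 called or 5 adjusted over the list, median 0.78, adjusted p = 0.00325, or 0.126 with estimated correlation), Th17 (2 of 8 called or 2 adjusted over the list, median 0.75, adjusted p = 0.000986, or 0.17 with estimated correlation) and follicular helper lists (3 of 15 called or 7 adjusted over the list, median 0.90, adjusted p = 6.76e-05, or 0.17 with estimated correlation) lay higher.

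Of 30 S phase genes tested, 3 rose (16 rose adjusted over the list), median 0.998 (adjusted p = 2.03e-07, or 0.329 with estimated correlation). Mcm6, a helicase subunit, rose (0.81 ± 0.22, adjusted p = 0.0221). Of 29 G2/M genes tested, 2 rose (26 rose adjusted over the list), median 2.22 (adjusted p = 1.45e-07, or 0.373 with estimated correlation). The division marker Mki67, at 1074 ± 974 against 273 ± 236 CPM (SD, n = 6 and n = 5), missed the threshold (log2 fold change 2.04 ± 0.77, adjusted p = 0.1). Of 17 glycolysis genes tested, 6 rose and 1 fell (11 rose and 1 fell adjusted over the list), median 0.29 (adjusted p = 6.33e-05, or 0.0802 with estimated correlation). The enzyme genes Tpi1 (1.11 ± 0.23) and Aldoa (0.65 ± 0.13) rose, and Pdk1, a pyruvate dehydrogenase kinase gene, fell (-0.72 ± 0.14, adjusted p of at most 0.00311). Of 35 oxidative phosphorylation genes tested, 3 rose (4 rose adjusted over the list), median 0.24 (adjusted p = 4.52e-05, or 0.17 with estimated correlation). The oxidase subunit Cox5b rose (0.70 ± 0.14, adjusted p = 0.00227).

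Summed G2/M transcripts were at 3983 to 6518 CPM in fl/fl post-tamoxifen libraries 1 to 3 and 416 to 699.6 CPM in libraries 4 to 6. In controls they were at 521 to 1887 CPM in 1 to 3 and 255 to 282 CPM in 4 and 5. Summed myeloid markers were at 132 to 1295 CPM in fl/fl and 51.9 to 861 CPM in control libraries. Summed B cell and plasma cell markers were at 523 to 1411 CPM in fl/fl libraries 1 to 3, 108 to 118 CPM in 4 to 6, and 35.2 to 600.2 CPM in controls. The B cell list did not pass (1 of 8 called or 1 adjusted over the list, median 0.93, adjusted p = 0.212, or 0.629 with estimated correlation), and its called member was Igj (4.30 ± 1.09, adjusted p = 0.0153), chosen after its values were seen. Its median was 1.85 in numbers 1 to 3 and -1.14 in 4 and above (adjusted p = 3.61e-05 and 0.00118, or 0.182 and 0.0557 with estimated correlation). The effector Treg median was 1.35 in numbers 1 to 3 and 0.62 in 4 and above (adjusted p = 1.72e-25 and 4.34e-15, or 0.037 and 0.0478 with estimated correlation). For inhibitory receptors it was 0.97 in numbers 1 to 3 and 0.56 in 4 and above (adjusted p = 0.000116 and 4.96e-07, or 0.0438 and 0.00912 with estimated correlation), and for G2/M genes 2.59 in numbers 1 to 3 and 1.06 in 4 and above (adjusted p = 2e-38 and 5.32e-08, or 0.037 and 0.0478 with estimated correlation). Leaving out 1 library changed the count to 396, 398 and 390 without control library 3, 4 or 5 and 418, 415, 411 and 1147 without fl/fl library 1, 2, 3 or 6. Calls were lost for Sesn1 without any 1 library except control library 2 and fl/fl libraries 4 and 6 (adjusted p up to 0.151), Gzmb without control library 3 (adjusted p = 0.0521), Il1rl1 without control library 3, 4 or 5 or fl/fl library 2 (adjusted p up to 0.0642), Ifngr2 without control library 3, 4 or 5 or fl/fl library 1, 2, 3 or 5 (adjusted p up to 0.187), Nkg7 without control library 3, 4 or 5 or fl/fl library 2 (adjusted p up to 0.0732), S100a6 without control library 3, 4 or 5 or fl/fl library 1 or 3 (adjusted p up to 0.0702), Mcm6 without control library 3, 4 or 5 or fl/fl library 1, 2 or 3 (adjusted p up to 0.0741), Actn1 without control library 3 or fl/fl library 1, 2 or 3 (adjusted p up to 0.0611) and Igj without fl/fl library 1 (adjusted p = 0.0991). A fit of the post-tamoxifen groups alone called 147 genes, losing Gzmb, Itgae, Il1rl1, Icos, Maf, Il10, Tigit, Ctla4, Lef1, Bach2, Foxp1, Ifngr2, Sesn1, Nkg7, S100a6, Mcm6, Actn1 and Igj (adjusted p up to 0.192). Numbers 1 to 3 alone gave 1325, losing Il1rl1, Batf and Ifngr2 (adjusted p up to 0.121), and numbers 4 and above 209, losing Gzmb, Il1rl1, Il10, Havcr2, Entpd1, Lef1, Foxp1, Tpi1, Aldoa, Pdk1, Nnt, Ifngr2, Sesn1, Nkg7, S100a6 and Actn1 (adjusted p up to 0.732). A fit without control numbers 2 and 3 gave 451, losing Gzmb, Havcr2, Ifngr2, Sesn1, Nkg7, S100a6, Mcm6, Actn1 and Igj (adjusted p up to 0.127). Sesn1 also missed the threshold with a CPM filter (adjusted p = 0.0551) and with no filter (adjusted p = 0.063), S100a6 with a myeloid term (adjusted p = 0.0736) and Igj with DESeq2 (adjusted p = 0.145). Within numbers 4 and above Igj turned to -1.93 (adjusted p = 0.485).

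**Figure D2:**
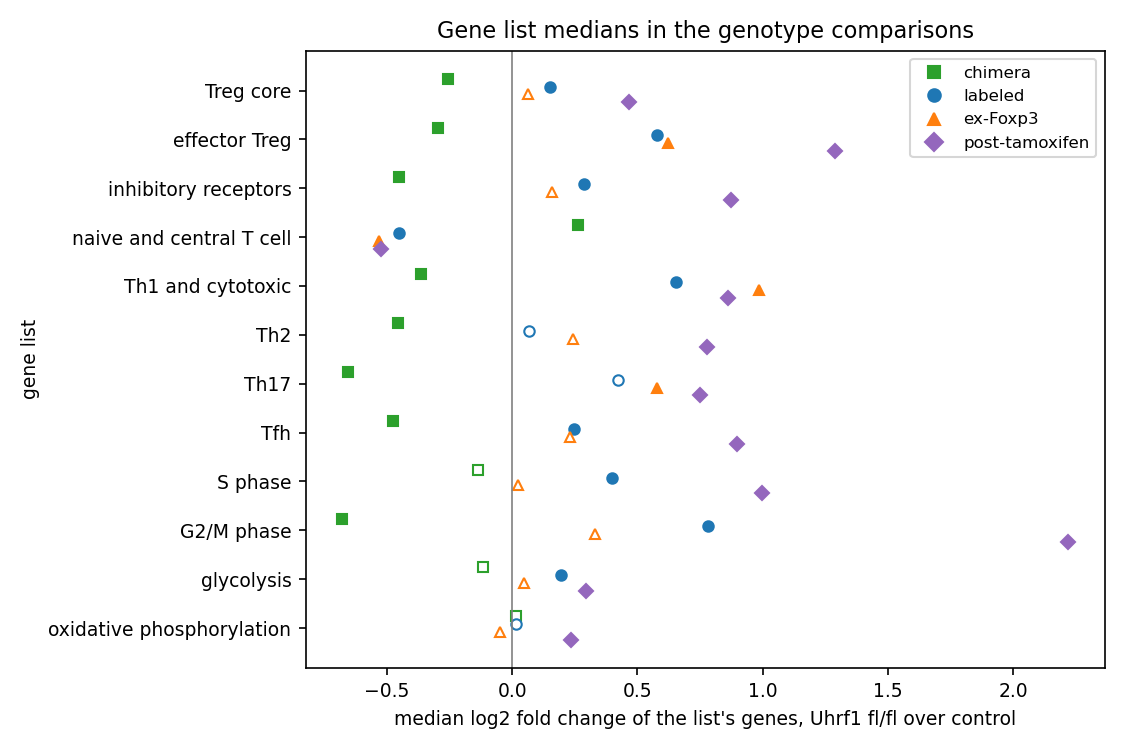
Median log2 fold change, Uhrf1-targeted against control, of 12 gene lists (vertical axis) in the 4 genotype comparisons, with filled symbols where the list test passed an adjusted p of 0.05 with the preset correlation. Effector Treg genes lie at -0.29 in the chimera and at 0.58, 0.62 and 1.29 in labeled, ex-Foxp3 and post-tamoxifen cells.

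Further lists were tested in the chimera, labeled, ex-Foxp3 and post-tamoxifen genotype comparisons, in that order. Genes of the DNA methylation machinery had medians of -0.0076, -0.028, -0.021 and -0.029 (adjusted p = 0.594, 0.802, 0.542 and 0.599). Germline genes that DNA methylation silences were mostly below the count filter, with 3 of 33 tested and none called (adjusted p = 0.754, 0.369, 0.178 and 0.733). Imprinted genes gave adjusted p = 0.754, 0.353, 0.823 and 0.291. Immediate early and heat shock genes gave adjusted p = 0.236, 0.894, 0.0904 and 0.607. CD8 T cell genes gave adjusted p = 0.594, 0.46, 0.787 and 0.854, and thymocyte genes adjusted p = 0.562, 0.0641, 0.484 and 0.212. Stromal, epithelial and endothelial genes gave adjusted p = 0.766, 0.353, 0.515 and 0.104, and myeloid and dendritic genes adjusted p = 0.85, 0.638, 0.305 and 0.607. NK and innate-like genes, tested in the pulse-chase libraries, gave adjusted p = 0.598, 0.567 and 0.733. Too few erythroid genes passed the filter for a test. NF-kB targets in post-tamoxifen cells included 3 that rose, although the list did not pass (adjusted p = 0.153).

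Ex-Foxp3 cells were compared with labeled cells of the same genotype, which kept Foxp3. In fl/fl mice Il2ra, the high-affinity interleukin receptor subunit, fell with Foxp3, at 110.4 ± 17.1 against 459 ± 55.7 CPM (SD, n = 6 each, log2 fold change -2.05 ± 0.23, adjusted p = 2.66e-06). Lrrc32 (-2.27 ± 0.36), which anchors latent TGF-beta, Ctla4 (-1.06 ± 0.17), Tnfrsf18 (-0.84 ± 0.14), which encodes GITR, Tnfrsf9 (-1.85 ± 0.35) and Itgae (-1.67 ± 0.42) fell as well (adjusted p of at most 0.0206). Tcf7, a transcription factor of naive and memory T cells, rose, at 1534 ± 160.5 against 734 ± 186 CPM (SD, n = 6 each, log2 fold change 1.06 ± 0.16, adjusted p = 0.000111). Themis (1.20 ± 0.14), a T cell receptor signalling gene, Tgfbr3 (1.60 ± 0.24), a TGF-beta coreceptor, and Rapgef4 (1.60 ± 0.22) also rose (adjusted p of at most 0.000113). In all 406 genes were called, 204 higher and 202 lower in ex-Foxp3 cells.

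In controls 35 genes were called, 19 higher and 16 lower. Il2ra (-1.51 ± 0.25), Tnfrsf18 (-0.78 ± 0.16), Socs2 (-1.18 ± 0.25), a signalling inhibitor, Tnfrsf8 (-1.67 ± 0.40) and Lamc1 (-1.02 ± 0.24), a laminin chain, fell (adjusted p of at most 0.0463). Tcf7 (0.90 ± 0.18), Themis (0.95 ± 0.15), Sidt1 (1.03 ± 0.16), an RNA transporter, Slamf6 (0.50 ± 0.11), a signalling receptor, and Pde7a (1.02 ± 0.22), a phosphodiesterase, rose (adjusted p of at most 0.0317). Of the 19 genes higher in controls, 18 were also higher in fl/fl mice, against 0.391 expected of independent lists (one-sided Fisher exact p = 3.78e-30). Of the 16 lower genes, 13 were shared against 0.326 expected (one-sided Fisher exact p = 3.73e-20). Fold changes correlated across 9921 genes, which are not independent replicates (Pearson r = 0.584, Spearman rho = 0.494). The difference of the changes between genotypes called 0 genes with edgeR, 236 at an unadjusted p below 0.05, and 0 with DESeq2. It gave -0.041 ± 0.90 for Uhrf1 and -0.73 ± 0.52 for Foxp3. Uhrf1 itself did not pass between ex-Foxp3 and labeled cells of fl/fl (-1.48 ± 0.62, adjusted p = 0.191) or control mice (-1.44 ± 0.67, adjusted p = 0.491).

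**Figure D3:**
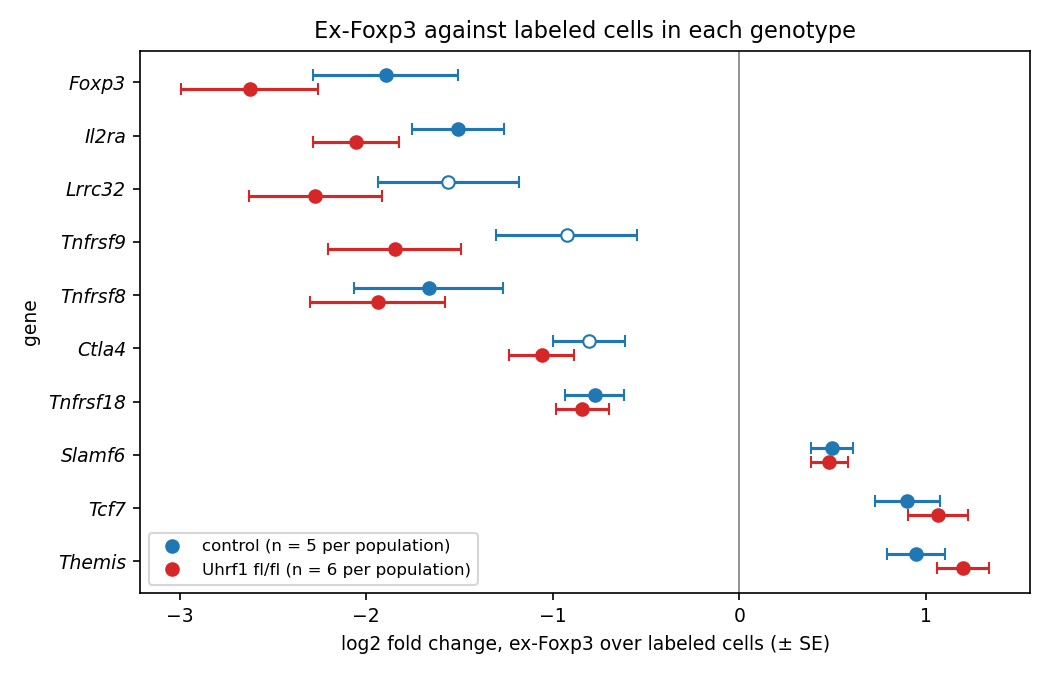
Log2 fold change with its SE of 10 genes, ex-Foxp3 against labeled cells, in fl/fl mice and in controls, with open symbols for values past no threshold. Foxp3 lies at -2.63 in fl/fl mice and -1.90 in controls.

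Among fl/fl libraries, of 29 Treg core genes tested, 16 fell (26 fell adjusted over the list), median -0.89 (adjusted p = 3.67e-38, or 0.000191 with estimated correlation). In controls, of 29 Treg core genes tested, 4 fell (19 fell adjusted over the list), median -0.82 (adjusted p = 7.12e-33, or 0.000564 with estimated correlation). The Treg core median was -1.04 in numbers 1 to 3 and -0.75 in 4 and above (adjusted p = 5.91e-26 and 5.6e-70, or 0.0202 and 0.000371 with estimated correlation) in fl/fl mice. In controls it was -0.80 in numbers 1 to 3 and -0.70 in 4 and above (adjusted p = 1.1e-20 and 3.12e-56, or 0.045 and 0.000667 with estimated correlation). In the fl/fl genotype, of 20 naive and central T cell genes tested, 5 rose (10 rose adjusted over the list), median 0.39 (adjusted p = 1.06e-06, or 0.191 with estimated correlation). Slamf6 (0.48 ± 0.10), Il6ra (0.72 ± 0.15), an interleukin receptor, and Klf2 (0.57 ± 0.16), a regulator of homing genes, rose (adjusted p of at most 0.0307). Among control libraries, of 20 tested, 2 rose (4 rose adjusted over the list), median 0.36 (adjusted p = 2.68e-09, or 0.0501 with estimated correlation). For fl/fl mice, of 28 effector Treg genes tested, 7 fell (1 rose and 9 fell adjusted over the list), median -0.29 (adjusted p = 4.79e-05, or 0.466 with estimated correlation). Tnfrsf8 (-1.94 ± 0.36) and Ccr8 (-1.73 ± 0.37), a chemokine receptor, fell (adjusted p of at most 0.00314). For controls, of 28 effector Treg genes tested, 1 fell (6 fell adjusted over the list), median -0.44 (adjusted p = 1.57e-07, or 0.451 with estimated correlation).

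Among fl/fl libraries, of 30 S phase genes tested, 4 fell (19 fell adjusted over the list), median -1.12 (adjusted p = 2.53e-11, or 0.251 with estimated correlation). The helicase subunit Mcm3 (-1.16 ± 0.27) and, outside the list, the multicopy histone Hist1h2bn (-3.51 ± 0.83) fell (adjusted p of at most 0.0135). The S phase median was -1.49 in numbers 1 to 3 and -0.26 in 4 and above (adjusted p = 1e-34 and 0.0179, or 0.02 and 0.306 with estimated correlation). G2/M genes lay lower there too (0 of 29 called or 21 adjusted over the list, median -2.06, adjusted p = 1.05e-07, or 0.466 with estimated correlation). In controls the S phase (0 of 30 called or 0 adjusted over the list, median -0.68, adjusted p = 1.3e-05, or 0.451 with estimated correlation) and G2/M lists (0 of 29 called or 0 adjusted over the list, median -1.39, adjusted p = 4.76e-07, or 0.451 with estimated correlation) lay lower. In the fl/fl genotype, of 21 NF-kB targets tested, 4 fell (7 fell adjusted over the list), median -0.24 (adjusted p = 5.63e-06, or 0.192 with estimated correlation). The subunit gene Nfkb2 fell (-0.59 ± 0.12, adjusted p = 0.00208). In controls, of 21 NF-kB targets tested, none passed (6 fell adjusted over the list), median -0.23 (adjusted p = 1.82e-05, or 0.188 with estimated correlation). Cx3cr1, a chemokine receptor of cytotoxic cells, rose in fl/fl mice from almost no reads, at 8.87 ± 6.70 against 0.347 ± 0.413 CPM (SD, n = 6 each, adjusted p = 0.00939).

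For fl/fl mice, leaving out 1 library changed the count to 242, 263 and 260 without ex-Foxp3 library 1, 2 or 3 and 262 without labeled library 2, and calls were lost for Klf2 without ex-Foxp3 library 1, 2 or 3 or labeled library 1, 3, 4, 5 or 6 (adjusted p up to 0.107) and Itgae without labeled library 1 or ex-Foxp3 library 3 or 6 (adjusted p up to 0.0539). For controls it changed to 12, 21, 15 and 19 without ex-Foxp3 library 1, 3, 4 or 5 and 4 and 10 without labeled library 2 or 3. The control calls lost were Tnfrsf18 without ex-Foxp3 library 1 or labeled library 2 or 3 (adjusted p up to 0.0865), Lamc1 without any 1 library (adjusted p up to 0.179), Pde7a without ex-Foxp3 library 1, 4 or 5 or labeled library 2 or 3 (adjusted p up to 0.141), Tnfrsf8 without any 1 library except labeled library 5 (adjusted p up to 0.191), Slamf6 without labeled library 1, 2 or 3 or ex-Foxp3 library 2, 4 or 5 (adjusted p up to 0.188), Socs2 without ex-Foxp3 library 2, 4 or 5 or labeled library 2 or 3 (adjusted p up to 0.0874) and Tcf7 without labeled library 2 (adjusted p = 0.0615). With the replicate number as a block, 893 genes were called in fl/fl mice and 211 in controls. Numbers 1 to 3 alone gave 521 in fl/fl mice, losing Slamf6 and Itgae (adjusted p up to 0.188), numbers 4 and above 179, losing Ccr8, Il6ra, Cx3cr1, Hist1h2bn, Nfkb2 and Klf2 (adjusted p up to 0.197), and a fit of the compared groups alone 437, losing Klf2 (adjusted p = 0.185). With no filter Klf2 (adjusted p = 0.0539) was not called. In controls numbers 1 to 3 gave 35, losing Foxp3, Il2ra, Tnfrsf18, Slamf6, Pde7a, Tnfrsf8 and Socs2 (adjusted p up to 0.323), numbers 4 and above 36, losing Tnfrsf18, Lamc1 and Tnfrsf8 (adjusted p up to 0.355), and the groups alone 137, losing Pde7a (adjusted p = 0.0615). Lamc1 and Pde7a also missed the threshold with no filter and with the myeloid term (adjusted p up to 0.0798). The thymocyte list lay higher in fl/fl mice (1 of 7 called or 1 adjusted over the list, median 0.19, adjusted p = 0.0126, or 0.207 with estimated correlation). In controls it gave adjusted p = 0.0884, and with the block adjusted p = 0.0496, or 0.295 with estimated correlation.

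Labeled cells were compared with post-tamoxifen cells of the same genotype, which can include Treg cells that arose after tamoxifen. In controls Il1rl1 was higher in labeled cells, at 183 ± 42.7 against 21.4 ± 23.4 CPM (SD, n = 5 each, log2 fold change 2.99 ± 0.50, adjusted p = 0.000537). Itgae (2.66 ± 0.51), Tigit (2.14 ± 0.39), Nrp1 (1.33 ± 0.25), Tnfrsf1b (1.04 ± 0.16) and Gata3 (0.58 ± 0.13), each of the Treg core or effector Treg list, were higher too (adjusted p of at most 0.00276). Lef1 (-1.04 ± 0.17), Actn1 (-1.22 ± 0.22), Bach2 (-1.19 ± 0.24) and S1pr1 (-0.68 ± 0.19), of the naive list, and Themis (-0.83 ± 0.15), of the thymocyte list, were lower (adjusted p of at most 0.0198). Tet3, a methylcytosine dioxygenase gene, was lower (-0.78 ± 0.12, adjusted p = 9.89e-05). Pdcd1 (1.141 ± 0.33), Tox2 (1.92 ± 0.41) and Ttn (2.30 ± 0.53) were higher (adjusted p of at most 0.0299). In all 787 genes were called, 395 higher and 392 lower in labeled cells.

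In fl/fl mice 454 genes were called, 178 higher and 276 lower in labeled cells. Tigit (1.27 ± 0.32), Tnfrsf1b (0.68 ± 0.15), Gata3 (0.51 ± 0.12), Batf (0.58 ± 0.15) and Ttn (2.14 ± 0.48) were higher (adjusted p of at most 0.0204). Actn1 (-1.43 ± 0.21), Ccr7 (-1.51 ± 0.25), a homing receptor, and Bach2 (-1.27 ± 0.24) were lower (adjusted p of at most 0.00226). Uhrf1 did not pass in controls (0.90 ± 0.66, adjusted p = 0.495) or fl/fl mice (-0.88 ± 0.57, adjusted p = 0.487). Foxp3 did not pass either (0.093 ± 0.37, adjusted p = 0.926 in controls, 0.14 ± 0.34, adjusted p = 0.896 in fl/fl mice).

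Among control libraries, of 20 naive and central T cell genes tested, 11 fell (14 fell adjusted over the list), median -0.63 (adjusted p = 1.46e-11, or 0.0191 with estimated correlation). For fl/fl mice, of 20 naive and central T cell genes tested, 7 fell (11 fell adjusted over the list), median -0.47 (adjusted p = 6.15e-11, or 0.0437 with estimated correlation). For controls, of 29 Treg core genes tested, 13 rose (15 rose and 1 fell adjusted over the list), median 0.61 (adjusted p = 3.95e-13, or 0.0345 with estimated correlation). Among fl/fl libraries, of 29 Treg core genes tested, 5 rose and 1 fell (6 rose and 1 fell adjusted over the list), median 0.36 (adjusted p = 1.26e-05, or 0.196 with estimated correlation). In controls, of 28 effector Treg genes tested, 12 rose (17 rose adjusted over the list), median 1.03 (adjusted p = 3.15e-17, or 0.0507 with estimated correlation). In the fl/fl genotype, of 28 effector Treg genes tested, 6 rose (10 rose adjusted over the list), median 0.42 (adjusted p = 1.41e-07, or 0.246 with estimated correlation). Th2 genes lay higher in labeled cells of controls (4 of 8 called or 5 adjusted over the list, median 1.05, adjusted p = 2.09e-06, or 0.0191 with estimated correlation) and fl/fl mice (1 of 8 called or 3 adjusted over the list, median 0.62, adjusted p = 0.00153, or 0.0802 with estimated correlation). Inhibitory receptors lay higher in controls (4 of 10 called or 4 adjusted over the list, median 0.36, adjusted p = 0.0015, or 0.0493 with estimated correlation). The naive median was -0.58 in numbers 1 to 3 and -0.78 in 4 and above (adjusted p = 6.03e-13 and 3.35e-16, or 0.0324 and 0.00795 with estimated correlation) in controls. For fl/fl mice it was -0.27 in numbers 1 to 3 and -0.66 in 4 and above (adjusted p = 0.00267 and 1.32e-25, or 0.297 and 0.00506 with estimated correlation).

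Markers of other cells were lower in labeled than in post-tamoxifen cells. The macrophage receptor Csf1r was at 7.14 ± 2.81 against 107 ± 77.3 CPM (SD, n = 5 each) in controls (log2 fold change -3.80 ± 0.80, adjusted p = 0.00294). In fl/fl mice it was at 4.70 ± 5.26 against 93.9 ± 106 CPM (SD, n = 6 each, log2 fold change -4.27 ± 0.78, adjusted p = 0.00206). Lrp1 gave -4.02 ± 0.72 in controls and -4.50 ± 0.71 in fl/fl mice (adjusted p = 0.00086 and 0.000881). Vcam1 (-3.38 ± 0.59) and Hmox1 (-3.19 ± 0.50), heme oxygenase, were lower in fl/fl mice (adjusted p of at most 0.00152). Complement C1qa was at 1.69 ± 0.836 against 29.6 ± 19.5 CPM (SD, n = 5 each) in controls (adjusted p = 0.00295). C1qa in fl/fl mice was at 0.147 ± 0.360 against 33.2 ± 39.6 CPM (SD, n = 6 each, adjusted p = 0.000603). Of the B cell list, H2-Aa was lower in controls (-3.93 ± 0.96, adjusted p = 0.00955) and H2-Ab1 in fl/fl mice (-3.87 ± 0.67, adjusted p = 0.00141). Sox4, of the thymocyte list, was at 2.72 ± 2.99 against 46.6 ± 26.1 CPM (SD, n = 5 each) in controls (adjusted p = 0.00271). Sox4 in fl/fl mice was at 0.396 ± 0.632 against 15.9 ± 9.32 CPM (SD, n = 6 each, adjusted p = 0.00323). The plasma cell gene Igj was at 0.129 ± 0.316 against 125 ± 184 CPM (SD, n = 6 each) in fl/fl mice (adjusted p = 0.00141).

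Among control libraries, of 17 myeloid and dendritic genes tested, 10 fell (1 rose and 13 fell adjusted over the list), median -3.10 (adjusted p = 1.94e-07, or 0.102 with estimated correlation). For fl/fl mice, of 17 myeloid and dendritic genes tested, 13 fell (15 fell adjusted over the list), median -3.98 (adjusted p = 1.71e-12, or 0.0437 with estimated correlation). For controls, of 8 B cell and plasma cell genes tested, 3 fell (3 fell adjusted over the list), median -2.83 (adjusted p = 0.00705, or 0.292 with estimated correlation). Among fl/fl libraries, of 8 B cell and plasma cell genes tested, 6 fell (7 fell adjusted over the list), median -4.15 (adjusted p = 5.32e-06, or 0.111 with estimated correlation). NK and innate-like genes were lower in controls (1 of 3 called or 3 adjusted over the list, median -2.94, adjusted p = 0.013, or 0.102 with estimated correlation) and fl/fl mice (2 of 3 called or 3 adjusted over the list, median -3.65, adjusted p = 0.00196, or 0.0655 with estimated correlation). Thymocyte genes, with Themis among them, were lower in controls (2 of 7 called or 2 adjusted over the list, median -0.52, adjusted p = 0.00855, or 0.102 with estimated correlation) and fl/fl mice (2 of 7 called or 5 adjusted over the list, median -0.52, adjusted p = 0.000871, or 0.0593 with estimated correlation). Control post-tamoxifen library 2 held summed myeloid markers at 51.9 CPM, its group's other libraries at 357 to 861 CPM, and control labeled cells at 60.8 to 73.2 CPM. With summed myeloid markers as a term, 545 genes were called in controls, losing Ttn, Tox2, Csf1r, Lrp1, C1qa, H2-Aa, Sox4, Pdcd1 and S1pr1 (adjusted p up to 0.559). In fl/fl mice 46 were, losing every gene named except Actn1, Ccr7, Bach2 and C1qa (adjusted p up to 0.734).

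**Figure D4:**
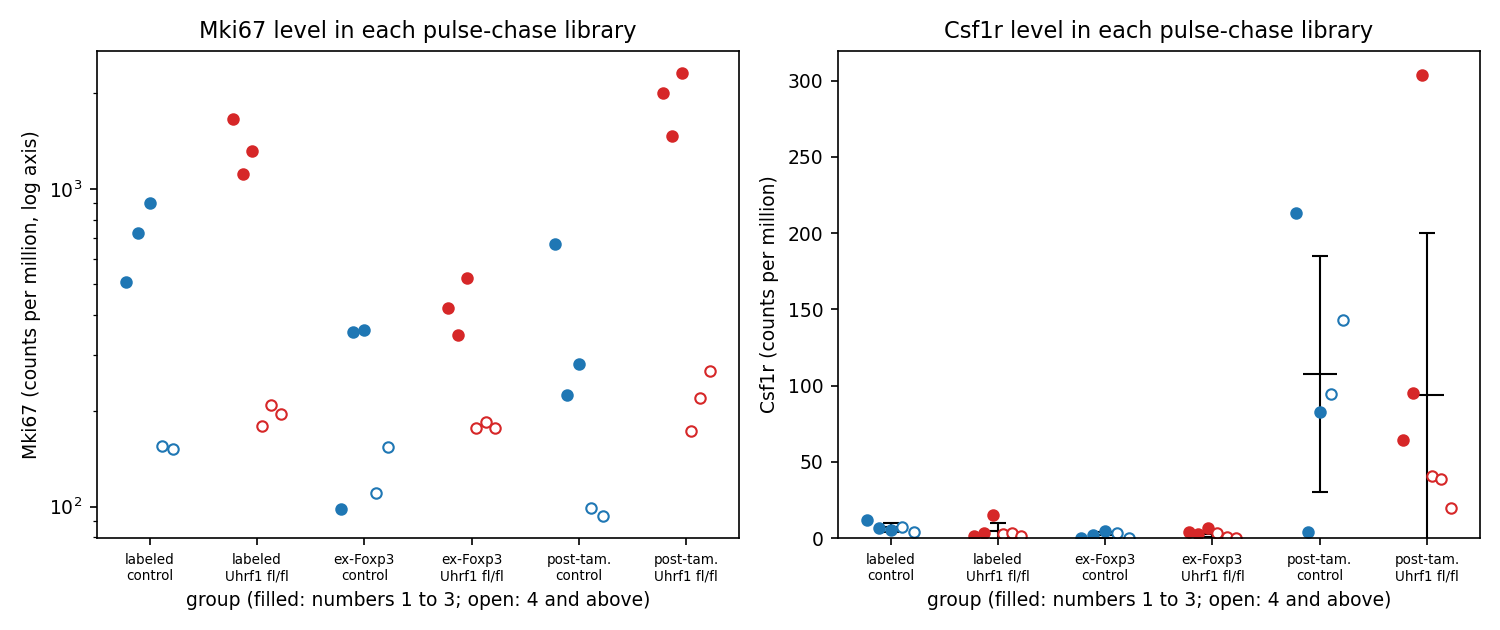
Levels in CPM of Mki67 (log axis) and Csf1r (linear axis, with mean and SD) in each pulse-chase library by group, with open circles for numbers 4 and above. Csf1r averages 107 and 93.9 CPM in post-tamoxifen cells of controls and fl/fl mice, and 7.14 and 4.70 CPM in labeled cells.

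For controls, leaving out 1 library changed the count to 491 and 520 without post-tamoxifen library 3 or 5, and calls were lost for Pdcd1 without post-tamoxifen library 1, 3 or 5 or labeled library 4 or 5 (adjusted p up to 0.09) and S1pr1 without post-tamoxifen library 3 or 5 or labeled library 4 or 5 (adjusted p up to 0.066). In fl/fl mice no single library moved the count by over 1.5 times, and the call of Batf was lost without post-tamoxifen library 2 or 6 or labeled library 5 (adjusted p up to 0.0538). There the replicate block called 805 genes. With it the follicular helper (adjusted p = 0.018 against 0.0804), S phase (0.0442 against 0.171) and G2/M lists (0.00532 against 0.163) passed, though not with estimated correlation (adjusted p = 0.494, 0.661 and 0.56). Numbers 1 to 3 alone gave 125 genes in controls, losing every gene named except Gata3, Lef1, Actn1, Tet3 and Themis (adjusted p up to 0.324), and 78 in fl/fl mice, losing every gene named except Actn1, Igj and H2-Ab1 (adjusted p up to 0.677). Numbers 4 and above gave 774 and 774, the latter losing Igj (adjusted p = 0.359). Fits of the compared groups alone gave 493 in controls, losing Ttn, Nrp1, Tigit and Pdcd1 (adjusted p up to 0.123), and 202 in fl/fl mice.

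The difference between labeled and post-tamoxifen cells itself differed by genotype in 2 genes, with 767 at an unadjusted p below 0.05. These were the interferon-inducible GTPase genes, close paralogs, Gbp3 (log2 fold change -1.06 ± 0.19, adjusted p = 0.014) and Gbp1 (-3.83 ± 0.72, adjusted p = 0.02). Gbp1 was chosen after its values were seen. Uhrf1 (-1.77 ± 0.87, adjusted p = 0.64) and Foxp3 (0.048 ± 0.50, adjusted p = 0.99) did not pass. Leaving out 1 library gave 1, 16, 0 and 0 without control post-tamoxifen library 1, 2, 3 or 4, 1 without control labeled library 5 and 1 and 1 without fl/fl post-tamoxifen library 3 or 5. The calls were lost for Gbp1 without control post-tamoxifen library 1, 3 or 4, control labeled library 5 or fl/fl post-tamoxifen library 3 or 5 (adjusted p up to 0.0897) and Gbp3 without control post-tamoxifen library 3 or 4 (adjusted p up to 0.0838). Numbers 1 to 3 alone gave 0 genes and numbers 4 and above 4, losing Gbp1 (adjusted p = 0.217). A fit of the compared groups alone lost Gbp3 (adjusted p = 0.0736), and a fit without control numbers 2 and 3 lost Gbp3 and Gbp1 (adjusted p up to 0.0674).

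Genotype effects were compared across 9440 genes tested in both experiments, which share no libraries. Fold changes in the chimera correlated negatively with those in labeled (Pearson r = -0.219, Spearman rho = -0.223), ex-Foxp3 (Pearson r = -0.177, Spearman rho = -0.167) and post-tamoxifen cells (Pearson r = -0.325, Spearman rho = -0.260). Genes are not independent replicates. Chimera controls and fl/fl post-tamoxifen libraries high in G2/M were kept, so no opposite effect of Uhrf1 deletion follows. Pydc3, the gene called in labeled cells, was not called in the chimera. Of the genes that rose in the chimera, 15 fell in post-tamoxifen cells, Bach2 among them, against 2.83 expected (one-sided Fisher exact p = 1.04e-07). In post-tamoxifen cells the 81 genes that rose and the 149 that fell in the chimera had medians of -0.31 and 0.54. Limma camera gave adjusted p of at most 1.44e-11, or 0.0116 with estimated correlation. In labeled cells the medians were -0.13 and 0.18 (adjusted p of at most 1.17e-05, or 0.138 with estimated correlation). In ex-Foxp3 cells they were -0.10 and 0.17 (adjusted p of at most 2e-07, or 0.0947 and 0.127 with estimated correlation).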

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

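Which genes entered the library checks (Il2ra, Mki67, Csf1r, Igj, Gbp1 and Gbp3 beside Uhrf1, Foxp3 and the total count) was chosen after results were seen, and the difference tests were planned. Dixon's test was run on 69 groups of values, of which 7 held a library apart from its group, against 3.45 by chance at 1 in 20. Another group, all but 1 value at 0, was left out, since the test passes there by construction. Uhrf1 stood apart among chimera controls in library 1, at 32.5 CPM. Among control labeled libraries the total count was lowest in 5, at 1153730. Foxp3 stood apart in fl/fl labeled library 5, at 508 CPM. Csf1r stood apart in fl/fl library 3 of post-tamoxifen (304 CPM) and labeled cells (15.3 CPM). Gbp1 was at 17.4 CPM in control labeled library 5. Igj was at 479 CPM in fl/fl post-tamoxifen library 1.

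Differences between genotypes in the labeled to post-tamoxifen change passed for Gbp1 (log2 -3.83) and Gbp3 (log2 -1.06). Gene lists passed with the preset correlation alone. For that change the medians were -0.36 for Treg core, -0.61 for effector Treg, -0.47 for Th2, -0.50 for Th17, -0.27 for follicular helper, -0.28 for inhibitory receptors, -0.11 for chemokine receptors and homing, -0.51 for S phase, -1.48 for G2/M phase, -0.26 for glycolysis and -0.18 for oxidative phosphorylation genes. With an estimated correlation these gave adjusted p = 0.487 to 0.806. For the ex-Foxp3 to labeled change the medians were -0.12 for Treg core and -0.38 for S phase genes (adjusted p = 0.928 with an estimated correlation for both).

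Y-linked transcripts, which no comparison uses, summed to 423 CPM in chimera control 1 and to 0 to 1.55 CPM in the other 7 chimera libraries, although the group is described as female. No explanation was tested.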

How the results depend on the processing

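The scaling, filter, DESeq2, block, group and left-out-library alternatives were planned, and the number-set, doubted-library and myeloid-term tests were chosen after the results were seen. Counts of called genes were 231 for the chimera, 1 for labeled genotype, 18 for ex-Foxp3 genotype, 717 for post-tamoxifen genotype, 35 for control ex-Foxp3 against labeled, 406 for fl/fl ex-Foxp3 against labeled, 787 for control labeled against post-tamoxifen, 454 for fl/fl labeled against post-tamoxifen, 0 for the ex-Foxp3 interaction (difference of differences) and 2 for the post-tamoxifen interaction. Other scaling factors left every count within 1.5 times. Of 133 called genes named, 36 passed under every alternative. Over 2845 refits of these, 2476 kept the call, 368 lost it and 1 turned direction. Losses were 0 with relative log expression or upper-quartile factors, 7 with no filter, 1 with a CPM filter, 3 with DESeq2, 1 with the replicate block and 25 of 99 in fits of the compared groups. In fits without 1 library, 200 of 1406 calls were lost. Within numbers 1 to 3, 44 of 105 were lost, and within numbers 4 and above 35. The myeloid term ended 24, leaving out control numbers 2 and 3 ended 17 of 38, and leaving out chimera controls 3 and 4 ended 12 of 28. Of genes named that were not called, 33 of 550 refits passed.

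With the replicate block the counts were 149 for labeled genotype, 229 for ex-Foxp3 genotype, 1650 for post-tamoxifen genotype, 211 for control ex-Foxp3 against labeled, 893 for fl/fl ex-Foxp3 against labeled, 1280 for control labeled against post-tamoxifen, 805 for fl/fl labeled against post-tamoxifen and 6 for the post-tamoxifen interaction, and the overlap between the genotypes was 168 genes. In the other comparisons the block kept counts within 1.5 times. Where all numbers deviated together, the calls it changed stand beside the results, and it changed no other call of a list or named gene there. Same-numbered libraries did not all deviate together in the chimera (-0.118 to 0.0307), the ex-Foxp3 (0.00331 to 0.181) and post-tamoxifen genotype (-0.166 to 0.278) and control labeled against post-tamoxifen comparisons (-0.0111 to 0.282). Pairs whose libraries correlated best with their own number were 0 of 4, 1 of 5, 2 of 5 and 3 of 5. In labeled genotype they were 2 of 5. For ex-Foxp3 against labeled control and fl/fl cells they were 4 of 5 and 5 of 6. For fl/fl labeled against post-tamoxifen they were 5 of 6. With the block Uhrf1 turned direction in comparisons where it was not called, to 0.011 for labeled genotype, to 0.0037 for ex-Foxp3 genotype and to 0.012 for the ex-Foxp3 interaction.

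Other moved counts were, with no filter, 396 for the chimera and 23 for control ex-Foxp3 against labeled. With DESeq2 they were 52 for labeled genotype, 89 for ex-Foxp3 genotype and 80 for control ex-Foxp3 against labeled. In fits of the compared groups they were 41 for labeled genotype, 137 for ex-Foxp3 genotype, 147 for post-tamoxifen genotype, 137 for control ex-Foxp3 against labeled, 493 for control labeled against post-tamoxifen, 202 for fl/fl labeled against post-tamoxifen and 1 for the post-tamoxifen interaction, and the overlap between genotypes was 90 genes. Without control post-tamoxifen library 2 in the fit they were 23 for labeled genotype, 48 for ex-Foxp3 genotype and 59 for control ex-Foxp3 against labeled. With the number set as a term they were 44 for labeled genotype, 112 for ex-Foxp3 genotype, 1420 for post-tamoxifen genotype, 81 for control ex-Foxp3 against labeled and 705 for fl/fl ex-Foxp3 against labeled. Numbers 1 to 3 alone gave 71 for labeled genotype, 143 for ex-Foxp3 genotype, 1325 for post-tamoxifen genotype, 125 for control labeled against post-tamoxifen, 78 for fl/fl labeled against post-tamoxifen and 0 for the post-tamoxifen interaction. Numbers 4 and above gave 7 for labeled genotype, 5 for ex-Foxp3 genotype, 209 for post-tamoxifen genotype, 179 for fl/fl ex-Foxp3 against labeled, 774 for fl/fl labeled against post-tamoxifen and 4 for the post-tamoxifen interaction. Without control numbers 2 and 3 they were 0 for labeled genotype, 5 for ex-Foxp3 genotype, 451 for post-tamoxifen genotype and 1 for the post-tamoxifen interaction. The myeloid term gave 31 for labeled genotype and 46 for fl/fl labeled against post-tamoxifen. Without chimera controls 3 and 4 the chimera gave 95. For all moved counts the cause was not tested, beyond the fewer libraries or genes of some fits.

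Leaving out each library gave 100 to 352 for the chimera, 1 to 9 for labeled genotype, 5 to 56 for ex-Foxp3 genotype, 390 to 1147 for post-tamoxifen genotype, 4 to 29 for control ex-Foxp3 against labeled, 242 to 433 for fl/fl ex-Foxp3 against labeled, 491 to 1114 for control labeled against post-tamoxifen, 318 to 459 for fl/fl labeled against post-tamoxifen, 0 to 0 for the ex-Foxp3 interaction and 0 to 16 for the post-tamoxifen interaction. Uhrf1 and Foxp3 turned direction in some of these fits where they were not called, with log2 ranges of Uhrf1 -0.48 to 0.22 for the ex-Foxp3 interaction, Uhrf1 -0.40 to 0.076 for ex-Foxp3 genotype, Foxp3 -0.12 to 0.25 for control labeled against post-tamoxifen, Foxp3 -0.36 to 0.039 for post-tamoxifen genotype, Foxp3 -0.12 to 0.27 for the post-tamoxifen interaction, Uhrf1 -0.41 to 0.28 for labeled genotype and Foxp3 -0.020 to 0.24 for fl/fl labeled against post-tamoxifen. Turned without a call within numbers 4 and above were Uhrf1 0.23 (labeled genotype), Uhrf1 0.17 (ex-Foxp3 genotype), Foxp3 0.022 (post-tamoxifen genotype), Igj -1.93 (post-tamoxifen genotype), Uhrf1 -0.19 (control labeled against post-tamoxifen), Foxp3 -0.044 (control labeled against post-tamoxifen), Foxp3 -0.087 (fl/fl labeled against post-tamoxifen) and Foxp3 -0.043 (the post-tamoxifen interaction). Within numbers 1 to 3 the value was Uhrf1 0.027 (labeled genotype). The number-set term gave Uhrf1 0.013 (labeled genotype) and Uhrf1 0.0019 (ex-Foxp3 genotype), leaving out control numbers 2 and 3 gave Uhrf1 0.64 (labeled genotype) and Uhrf1 0.050 (ex-Foxp3 genotype), and the myeloid term gave Foxp3 -0.15 (control labeled against post-tamoxifen), Uhrf1 0.99 (fl/fl labeled against post-tamoxifen) and Foxp3 -0.073 (fl/fl labeled against post-tamoxifen). The cause was not tested.

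List tests past the threshold numbered 102, 14 with an estimated correlation, and 113 with the replicate block. At these depths 9569 and 9921 of 19434 genes had enough reads to be tested.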

Other observations

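The split and explanation tests given here were chosen or specified after the results were seen. Estimates of Nnt, Ifngr2, Sesn1 and Pydc3, picked after seeing values, were below 0 in fl/fl mice in every pulse-chase population, though not all passed. Nnt, a transhydrogenase gene partly deleted in some laboratory substrains, gave -0.70 ± 0.15, adjusted p = 0.0617 in labeled and -0.86 ± 0.15, adjusted p = 0.000671 in post-tamoxifen cells, Ifngr2 -1.01 ± 0.24, adjusted p = 0.0731 and -0.73 ± 0.22, adjusted p = 0.0395, and Sesn1 -0.72 ± 0.18, adjusted p = 0.114 and -0.57 ± 0.18, adjusted p = 0.0466. Pydc3 gave -0.55 ± 0.14, adjusted p = 0.0941 in ex-Foxp3 and -1.06 ± 0.15, adjusted p = 5.16e-05 in post-tamoxifen cells. With the number as a block, pairing no mice here, labeled cells gave adjusted p = 0.0135 for Nnt, 0.0244 for Ifngr2 and 0.0143 for Sesn1 (edgeR). No explanation was tested.

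Control post-tamoxifen library 2 held Foxp3 at 123 and Il2ra at 214 CPM, control ex-Foxp3 libraries at 79.4 to 151 and 179 to 201 CPM, and control labeled libraries at 388 to 428 and 468 to 643 CPM. On genes that separate the other post-tamoxifen (position 0) from the ex-Foxp3 control libraries (position 1), its median position was 0.900, within the ex-Foxp3 range of 0.667 to 1.10 and outside the -0.154 to 0.344 of its group. On genes that separate labeled (0) from ex-Foxp3 libraries (1) it lay at 0.872, within the ranges of ex-Foxp3 libraries (0.499 to 1.27) and of its own group (0.357 to 1.24), so this scale sets it apart from labeled libraries (-0.0228 to 0.663) alone. An exchange with ex-Foxp3 library 2 is argued against by that library's position of 1.003 on the first scale, and low depth by a total of 3153563 counts. A wrong label, or a sort gate that took ex-Foxp3 cells, stays a candidate explanation for this single library, and no biological explanation was tested.

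Pulse-chase numbers 1 to 3 differed from numbers 4 and above, with 555 genes called in fl/fl labeled, 1315 in fl/fl post-tamoxifen, 181 in fl/fl ex-Foxp3 and 167 in control labeled cells, but 2 in control ex-Foxp3 and 0 in control post-tamoxifen cells (edgeR, 512 at an unadjusted p below 0.05). G2/M genes lay higher in 1 to 3 in all 6 groups, with log2 medians of 1.24 to 3.45 (adjusted p = 0.000325 to 0.125 with an estimated correlation). So did genes of the B cell and plasma cell list (median 3.18) and effector Treg genes (1.18) in fl/fl post-tamoxifen cells, where naive genes lay lower (-0.53, adjusted p of at most 0.0496 with an estimated correlation). Library depth is argued against, since numbers 1 to 3 had the larger mean total in 2 of 6 groups, and mouse sex by the 555 genes called in fl/fl labeled cells, all without Y-linked reads. Differences in labeled cells of the genotypes correlated across genes (r = 0.487), which is consistent with a batch or cohort shared by a number set, although the labels give no batch and the same age for all, and no biological difference between cohorts was tested.

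Post-tamoxifen cells had more genotype calls than labeled cells (717 and 1). The gap depends on the fit (147 and 41 in fits of the compared groups alone). The planned test of it called 2 genes. Myeloid RNA as the whole cause is argued against by 647 of 717 calls kept with a myeloid term. So are the number sets, by 209 and 1325 genes called within them, though overlap with the 717 was not counted. Where 209 were called, B cell and plasma cell genes lay lower in fl/fl mice (median -1.14). Mouse sex as the whole cause is argued against by 367 of 717 calls kept without control numbers 2 and 3. The same holds of control library 2, with 607 kept without it (907 called). Still open are, among others, mouse sex in part, line differences, B cell and plasma cell RNA and division state (not used as terms). A genotype effect that may reach unlabeled cells stays an untested hypothesis.

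Splits of the libraries into other groups of the same sizes were refitted on the compared groups alone. In the chimera 1 of 35 splits, the real one, called as many genes (231, highest other 9). In the other comparisons 100 splits were drawn, the number-set split apart. The real split alone called as many genes for ex-Foxp3 genotype (real 137, highest other 77) and post-tamoxifen genotype (147 and 40). It did so too for ex-Foxp3 against labeled in controls (137 and 134) and fl/fl mice (437 and 86). The same held for labeled against post-tamoxifen in controls (493 and 94) and fl/fl mice (202 and 55). Unadjusted shares under 0.05 argue against chance for these, apart from both comparisons within controls. There numbers pair the libraries, and 16 splits parting all pairs are too few for a share under 0.05. For labeled genotype 3 of 100 splits called as many (41, highest other 266), and for the post-tamoxifen difference of differences 3 of 100 (1, highest other 2), both under 0.05. For the ex-Foxp3 difference of differences the real count was 0 (highest other 5). All 100 splits reach it, so nothing follows about chance.

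A split of labeled cells by number set called 682 genes, more than the genotype split, and of labeled and post-tamoxifen fl/fl cells 1231, which points to a structure of the libraries. Within number sets, labeled genotype called 71 and 7 genes and fl/fl labeled against post-tamoxifen 78 and 774. Among splits parting all same numbers, only the real one called as many genes. The highest other called 0 for control and 1 for fl/fl ex-Foxp3 against labeled (16 and 32 splits). It called 0 for fl/fl labeled against post-tamoxifen (32) and 27 for labeled genotype (32), whose same numbers are not the same mouse.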
